A study of Rattus norvegicus with 12 samples.

How the data were processed

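The series profiled N6-methyladenosine (m6A), a methyl mark on adenosines inside mRNA, in the retina of male Sprague-Dawley rats. Per the labels' protocols, diabetes was induced with streptozotocin, a compound toxic to pancreatic beta cells, at 60 mg/kg on 5 days after a 12 h fast, and control rats received citrate vehicle. A rat counted as diabetic when its blood glucose exceeded 16.7 mmol/L. RNA was cut to fragments of about 100 nt and immunoprecipitated with a polyclonal anti-m6A antibody, and part of the RNA was kept as input. The 12 samples comprised immunoprecipitation (IP) and input libraries of 3 control and 3 diabetic animals. The 6 IP samples came with a peak list each and entered every comparison. The 6 input samples entered only as the background of those lists.

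Per the submitters' processing notes, the tools were CASAVA, fastp 0.19.11, BWA 0.7.12 and MACS2 2.1.0. Per the file headers, the authors called peaks with MACS separately for each animal, its IP library against its own input, with a q cut-off of 0.05, no shifting model, an extension size of 118 to 125 bases, all duplicate reads kept, summits called within regions, and the larger library scaled to the smaller. Replicates were not pooled. The effective genome size given to the caller was 61.5 Mb, per the file headers. BWA does not split reads over introns, so reads over exon junctions can be lost or clipped, and the kept duplicates count toward every peak. The caller was not given the strand, and no strand is recorded for the peaks.

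The values used were of 4 kinds. The pileup is a coverage signal at the summit that the authors' caller wrote after scaling. The deposited −log10 p and −log10 q of each summit compare that pileup with the local background from input. The headers of both columns hold a spreadsheet error in all 6 files, so they were told apart by the column order of MACS and by their values. The fold enrichment is the authors' ratio of pileup to that background. Fold enrichment and −log10 values are the authors' own values for each peak, and they served here only to describe, rank or filter peaks within a list. Per the file headers, the local background is the highest of a genome-wide floor and averages over 1 kb and 10 kb of input. It was computed back from pileup and fold enrichment and divided by the floor of the library.

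A region called with several summits fills several lines of a file. These lines were joined, so a region counted once, with the fold enrichment of its summit with the highest −log10 p. Regions of the 6 lists that overlapped by at least 1 base were merged into union regions. A union region was diabetic-only when all 3 diabetic libraries and no control library had a peak in it, and control-only in the opposite case. Overlap of lists was measured as the Jaccard index, the bases covered in both lists divided by the bases covered in either. Group means of regions and covered length were compared with exact two-sided permutation tests. With 3 animals against 3, these cannot give a p below 0.1. The mean Jaccard index within groups minus that between groups was ranked among the 10 distinct splits of the 6 libraries (exact, one-sided), with the same smallest p. The number of group-only regions was set against the other 9 splits. Fisher's exact test of 3 of 3 against 0 of 3 gives p = 0.1 for a single region, so no region can pass 0.05. Shares carry Wilson 95% intervals, and all intervals cover counting error only.

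The numbers of reads in IP and input libraries set how weak a peak could be called. The smaller library of each animal, to which the other was scaled, held 8175227 to 12354616 reads. The weakest call over the genome-wide floor had a fold enrichment between 1.85 and 2.03 in the 6 libraries. At the floor, enrichment below that was not detectable at this depth. Where the local background lay above the floor, regions were called down to fold enrichments of 1.10 to 1.40.

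The peak files and labels name no genome build. The last peak on chromosome 1 ended at 282 Mb, past the last gene of that chromosome in the rat gene table used for names (assembly GRCr8), so builds differ and positions could not be turned into gene names. Coordinates are those of the peak files, 1-based. Gene-level comparisons, the 29 gene lists chosen for the retina, transcript locations and DRACH motifs were therefore not analysed here. The regions named follow a rule fixed with the other main choices before the data were examined. It takes 15 diabetic-only regions, 15 control-only regions and 10 regions shared by all 6 libraries, each with the highest value of the lowest within-list fold enrichment percentile. The rule was written for genes, with regions as its fallback; its parts on list members were not applicable.

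The alternatives were a −log10 q of at least 5, a fold enrichment of at least 3, lists of equal length (the 9082 regions with the highest −log10 p in each), assembled nuclear chromosomes only, a reciprocal overlap of 50%, merging over gaps of 100 bases, leaving out each library, and a block on replicate number. Further ones were added after the data were seen: strict presence with lenient absence, windows of 50 bases either side of summits, and removal of regions with a local background over 3 times the floor. A model with 1 sensitivity per library, fitted by conditional likelihood to regions found in 1, 2, 4 or 5 libraries, gave the number of regions expected in each combination of 3 libraries; it was also added afterwards. For 1 window, the regions of a library were taken to the depth of the others by a Poisson model at the lowest −log10 p called in each list. The counting of group-only regions was tested on simulated data with 12467 regions. It recovered 200 of 200 planted diabetic-only and 100 of 100 planted control-only regions, with 84 and 34 other regions meeting the same definitions by chance. Planted regions met the definition by design, so this checks the merging and counting and says nothing about the detection of real group-only regions. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.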

Results

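Peak lists of m6A-enriched RNA regions were compared between retinas of 3 streptozotocin-diabetic and 3 vehicle-treated control rats, to see where the retinal m6A map differs in experimental diabetes. According to the labels each IP library came from a separate animal. The animals weighed 107 ± 3.59 g (SD, n = 3) in the control group and 102 ± 1.81 g (SD, n = 3) in the diabetic group. The IP libraries of control replicates 1, 2 and 3 held 8661200, 16114422 and 9030946 reads, and those of the diabetic replicates 12934276, 16017442 and 12675809. The matching inputs held 12010766, 8175227 and 10102647 reads in controls and 8729247, 10186285 and 12354616 in diabetic animals. The smaller library of each animal, which sets the depth of its peak list, was on average deeper in the diabetic group (n = 3 each; exact two-sided permutation p = 0.2).

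The number of m6A regions per retina did not differ detectably between diabetic and control animals. Control lists held 9082, 9103 and 10160 regions, and diabetic lists held 9731, 10552 and 9998. The means were 9448 ± 616 and 10094 ± 419 regions (SD, n = 3 each), a difference of 645 regions that is larger than either SD, while the ranges of the groups overlap (exact two-sided permutation p = 0.3; the smallest p for 3 against 3 is 0.1). The regions covered 3.62 ± 0.431 Mb in controls and 3.90 ± 0.189 Mb in diabetic retinas, a difference of 0.282 Mb (SD, n = 3 each; exact permutation p = 0.4). Without control replicate 3 the difference rose to 1001 regions and to 0.530 Mb (exact permutation p = 0.1 for each, the smallest possible for 2 against 3), and without diabetic replicate 2 it was 416 regions. Leaving out control replicate 1 or 2 gave 0.177 and 0.139 Mb, and leaving out diabetic replicate 2 gave 0.175 Mb. With a fold enrichment of at least 3 the difference was 319.7 regions, and with equal list lengths it was 0.166 Mb.

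Width and summit number of the regions did not differ detectably between groups. The median width was 289 ± 13.3 bases in controls and 295 ± 2.65 bases in diabetic animals (SD, n = 3 each; exact permutation p = 0.4). Regions with several summits made up 32.4% ± 1.74 of the control lists and 32.4% ± 0.388 of the diabetic lists (SD, n = 3 each; exact permutation p = 1). Within single lists the median fold enrichment over the background lay between 4.74 and 5.17. For most regions of each list that background was the genome-wide floor, so their fold does not correct for local input.

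**Figure D1:**
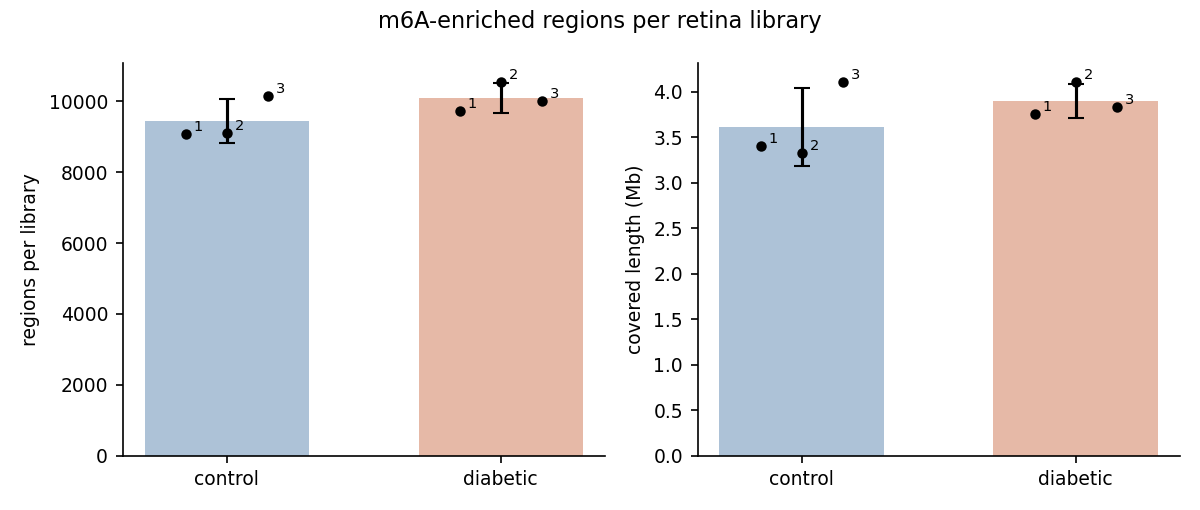
Number of called m6A regions (left) and covered length in Mb (right) in control and diabetic retinas; bars are group means, error bars the SD of 3 animals, and points single animals with their replicate number. Control replicate 3, with 10160 regions, lies inside the diabetic range of 9731 to 10552 regions. Its covered length of 4.11 Mb is slightly above the highest diabetic value, also 4.11 Mb when rounded, in diabetic replicate 2.

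Across 6 libraries, list length was also set against read numbers. The number of regions was related to the reads of the smaller library with Pearson's r = 0.549 (exact permutation p = 0.236, Benjamini-Hochberg adjusted p = 0.708 over 3 relations) and Spearman's rho = 0.771 (exact permutation p = 0.103). Without the 2 libraries farthest from the median number of reads, r was 0.816. For IP reads r was 0.173 and rho 0.2 (exact permutation p = 0.710 and 0.714), and for input reads r was 0.122 and rho 0.143 (exact permutation p = 0.794 and 0.803). Without the 2 farthest libraries these r were -0.0662 and -0.497. Each group has too few libraries for a value of its own.

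Most m6A regions were common to diabetic and control retinas. The 6 lists merged into 12467 union regions, of which 7098 (56.9%) had a peak in all 6 libraries and 9996 (80.2%) had a peak in at least 1 library of each group. Regions found in a single library numbered 1848. The shared regions were broad and strong, with a median width of 437 bases and a median fold enrichment of 6.30. The region with the highest value of its lowest enrichment percentile over the lists lay on chromosome 10 from 34534703 to 34536248, 1546 bases long, with fold enrichments of 46.5 to 68.5 over the 6 libraries. It was followed by regions on chromosome 11 from 34955494 to 34956331 (38.9 to 54.6), chromosome 7 from 41220134 to 41220889 (36.6 to 53.4), chromosome 7 from 123238397 to 123239152 (37.6 to 52.3) and chromosome 3 from 117938572 to 117939770 (33.0 to 43.7). The next in rank lay on chromosome 5 from 151905786 to 151907732, chromosome 9 from 16405248 to 16406338, chromosome 16 from 73944859 to 73946253, chromosome 10 from 106719204 to 106721755 and chromosome 8 from 75606848 to 75607811. All 10 were among the top 1 percent of every list, with lowest percentiles from 99.5 to 99.9. No gene, exon or UTR is given for these or later positions, because an annotation of the build of the peak files was not used here.

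The lists of the 3 diabetic animals overlapped one another more closely than the control lists did. The Jaccard index of covered bases averaged 0.809 ± 0.0116 over the 3 pairs of diabetic libraries, 0.741 ± 0.0161 over the 3 pairs of control libraries and 0.760 ± 0.0272 over the 9 pairs between groups (SD over pairs, which share libraries; this order was not tested by itself). The mean within groups exceeded the mean between groups by 0.0156. In 2 of the 10 splits of the libraries the excess was as large (exact one-sided p = 0.2), the highest of the others being 0.0172, for the split that exchanges control replicate 3 and diabetic replicate 1. Control replicate 3 overlapped the diabetic lists more, at a mean of 0.791, than the other control lists, at 0.732. Without control replicate 3 the excess was 0.0528, and it was -0.000781, -0.00120 and -0.00206 without diabetic replicates 1, 2 and 3. Without control replicate 2 it was 0.0266. The mean within groups weights every pair alike. Without a diabetic library the lower control pairs outnumber the remaining diabetic pair, and without a control library the reverse holds. Changes of the excess, including its sign, follow in part from these weights and cannot measure dependence on a library.

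**Figure D2:**
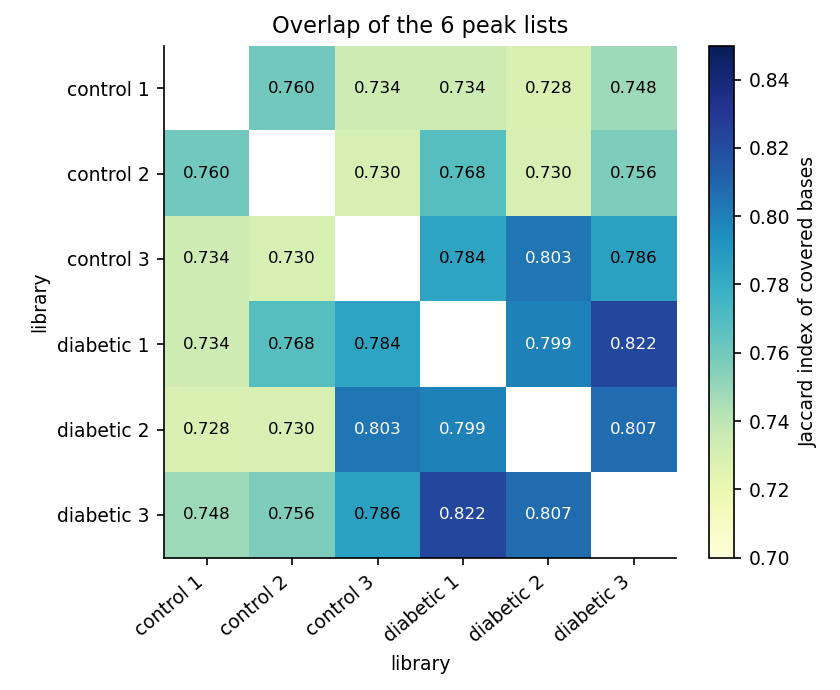
Jaccard index of covered bases for each pair of the 6 libraries (rows and columns are libraries, colour and printed value the index, which has no unit). The 3 diabetic pairs range from 0.799 to 0.822, and control replicate 3 has 0.784 to 0.803 with diabetic libraries against 0.730 and 0.734 with controls.

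Few regions separated the groups, and more of them were found in diabetic retinas. Diabetic-only regions, with a peak in all 3 diabetic and no control libraries, numbered 137 (1.10% of the union), and control-only regions numbered 25 (0.201%). Another combination of 3 libraries, control replicate 3 with diabetic replicates 2 and 3, had 133 regions of its own. The model with 1 sensitivity per library expected 71.5 diabetic-only and 15.1 control-only regions. With equal list lengths there were 84 diabetic-only and 46 control-only regions, and with a fold enrichment of at least 3 there were 87 and 19. An alternative chosen after seeing the data, with a −log10 q of at least 5 for presence and the authors' threshold for absence, gave 85 and 17, and windows around summits, also chosen then, gave 204 and 44. Without control replicate 3, 467 regions were diabetic-only, and without diabetic replicates 1, 2 and 3 the numbers were 246, 220 and 228. Control-only regions numbered 59, 93 and 105 without control replicates 1, 2 and 3 and 59 without diabetic replicate 2. A definition over fewer libraries is easier to meet.

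**Figure D3:**
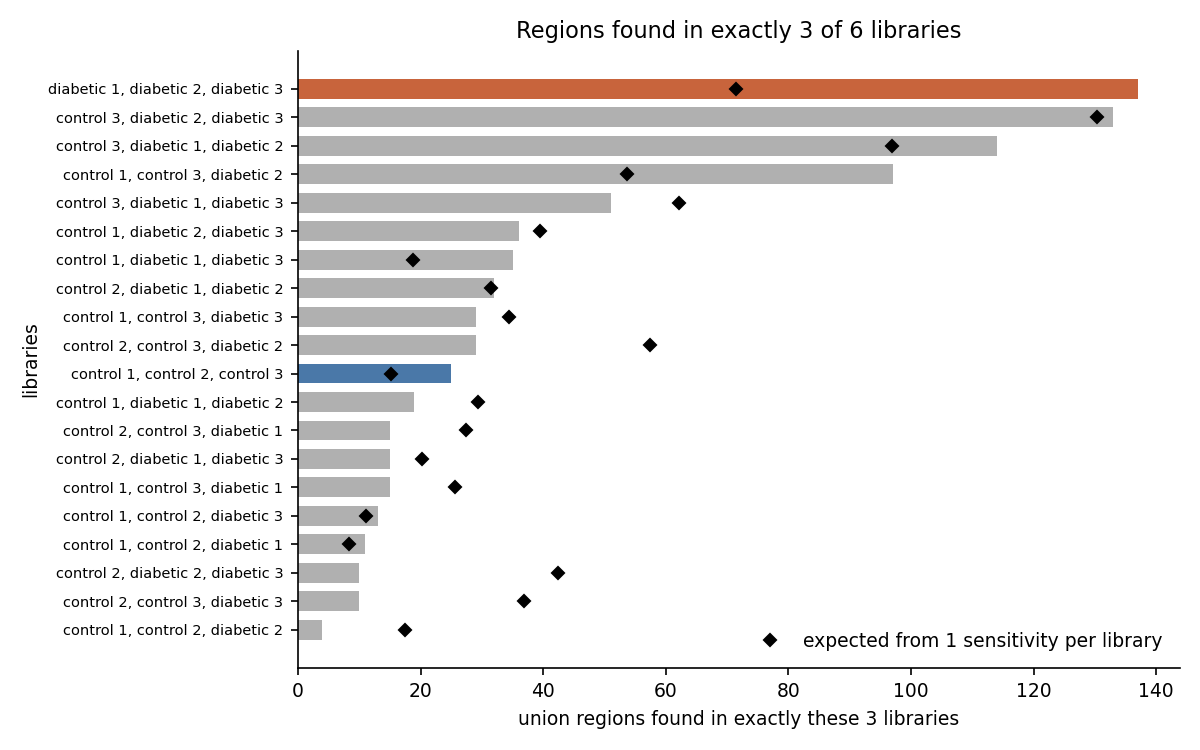
Number of union regions found in exactly the 3 named libraries (horizontal axis) for each of the 20 combinations of 3 among 6 libraries. Bars are observed numbers, with the diabetic-only combination in orange and the control-only combination in blue, and diamonds the numbers expected from 1 sensitivity per library. Diabetic-only regions lead with 137 observed and 71.5 expected, next to 133 observed and 130 expected for control replicate 3 with diabetic replicates 2 and 3.

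Group-only regions were narrow and weakly enriched. Diabetic-only regions had a median width of 198 bases and a median fold enrichment of 2.82, and control-only regions 198 bases and 2.99. The other 668 regions found in exactly 3 libraries had 202 bases and 2.89. A fold enrichment over 5 in any library was reached by 3 of the 137 diabetic-only and 3 of the 25 control-only regions. Within 1 kb of a region shared by all 6 libraries lay 24 diabetic-only regions (17.5%, Wilson 95% interval 12.1 to 24.7%) and 3 control-only regions (12%, 4.17 to 30.0%). Among the other regions found in exactly 3 libraries the share was 19.5% (16.6 to 22.6%), so the intervals overlap.

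The leading diabetic-only region lay on chromosome 3 from 147814429 to 147814656, with fold enrichments of 3.89 to 5.99 in the 3 diabetic lists. The next lay on chromosome 14 from 19405279 to 19405439 (3.98 to 4.48), 778 bases from a shared region. Regions on chromosome 11 from 68142851 to 68143018 (3.92 to 4.43) and chromosome 19 from 14722473 to 14722632 (3.93 to 4.48) were over 100 kb from any shared region. Then came chromosome 16 from 20555288 to 20555472 (3.55 to 4.11), chromosome 9 from 99056685 to 99056826 (3.62 to 3.70) and chromosome 1 from 41646958 to 41647124 (3.33 to 4.63). The remaining 8 named regions lay on chromosome 1 from 265263816 to 265263963, chromosome 6 from 10386841 to 10387217, chromosome 8 from 75616057 to 75616205, chromosome 17 from 80332574 to 80332924, chromosome 3 from 62802156 to 62802550, chromosome 4 from 56697359 to 56697510, chromosome 3 from 177340028 to 177340195 and chromosome 10 from 90551892 to 90552035. Their positions within the lists were low to middling, with lowest percentiles of 21.4 to 38.1 over the 15 regions. For each of them Fisher's exact test gives p = 0.1, the smallest value possible.

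In control animals the leading region lay on chromosome 6 from 3388337 to 3388530, with fold enrichments of 4.0 to 5.84 in the 3 control lists. It was followed by chromosome 1 from 100953524 to 100953882 (3.93 to 6.25), chromosome 5 from 156400502 to 156400664 (3.47 to 4.23), chromosome 1 from 128980549 to 128980694 (3.41 to 4.81) and chromosome 20 from 50150683 to 50150878 (3.28 to 4.29). Both chromosome 2 regions, from 262907094 to 262907268 and from 262907439 to 262907650, were neighbours. The other 8 lay on chromosome 8 from 64109486 to 64109772, chromosome 18 from 16975766 to 16976029, chromosome 1 from 143035312 to 143035485, chromosome 20 from 11481942 to 11482139, chromosome 8 from 48620008 to 48620156, chromosome 14 from 81382475 to 81382636, chromosome 6 from 108032228 to 108032414 and chromosome 9 from 105634958 to 105635208. Lowest percentiles of these 15 regions were 7.17 to 36.6. With a fold enrichment of at least 3, 8 of the 15 no longer had a peak in all 3 control lists, and with equal list lengths 3 did not.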

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

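No exact permutation test of regions per library, covered length or similarity passed 0.05 under any alternative run, which these group sizes cannot reach. Differences in regions and covered length kept their direction in 10 and 11 alternatives. These include the replicate block, which cannot change the differences. Leaving out 1 library gave differences of 416 to 1001 regions and 0.139 to 0.530 Mb, and an excess of within-group over between-group Jaccard index of -0.00206 to 0.0528, below 0 without any 1 diabetic library. This excess shifts with the numbers of control and diabetic pairs left, so its change of sign cannot be read as dependence on a diabetic library. Shared regions stayed within 1.5 times of 7098 in all 12 alternatives. Diabetic-only regions numbered 87 with a fold enrichment of at least 3, 84 with equal list lengths, 169 to 467 without 1 library, and 85 with strict presence and lenient absence. Control-only regions numbered 46 with equal list lengths, 34 to 105 without 1 library, and 44 with summit windows. Strict presence and summit windows were chosen after seeing the data, as was removal of high local background (131 and 27). Shorter lists and looser definitions move these counts by construction; the cause was not tested further. The larger side of another split exceeded the diabetic-only count with a −log10 q of at least 5 (133 against 119), a fold of at least 3 (99 against 87) and reciprocal overlap (157 against 155), and stayed below it with equal lengths (70 against 84). Of the 15 control-only regions named, 8 lost the peak of at least 1 control library with a fold of at least 3, and 3 with equal lengths. Gaps of 100 bases closed nothing within lists. Under the replicate block the differences stay at 645 regions and 0.282 Mb by construction, and only the p can differ. The exact permutation p was 0.5 for both (smallest possible 0.25). Deviations of same-numbered libraries correlated at -0.0549, -0.114 and -0.0620, against -0.0744 to 0.130 for other pairs. No pairing by number was seen, but so few pairs cannot exclude it. Equal lengths fix the number of regions, so that test was not run. The planned results on genes, gene lists, transcript location and DRACH motifs and their alternatives were not run, because a genome and annotation of the build were not used here. Depth limits the weakest calls, which over the floor had fold enrichments of 1.85 to 2.03. Most group-only regions lay above that, with medians of 2.82 (diabetic-only) and 2.99 (control-only) and lower quartiles of 2.54 and 2.70. Their enrichment in the libraries without a peak is not known from the lists.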

Other observations

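The test of library sensitivity against the number of diabetic-only regions and the test of list length for control replicate 3 were set before their results were seen; the other tests here were chosen after.

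The shares of m6A regions on single chromosomes differed between the group means by at most 0.294 percentage points, on chromosome X (2.03% ± 0.0930 in controls and 2.33% ± 0.238 in diabetic animals; SD, n = 3 each; exact permutation p = 0.2). Part of this lay in 1 window, from 2000001 to 3000000, described below. Outside it the X shares were 2.09, 1.94 and 1.97% in controls and 2.32, 2.03 and 2.29% in diabetic animals. On 7 of 23 chromosomes the 3 diabetic shares lay all above or all below the control shares, where chance gives 10%, each with an exact two-sided permutation p of 0.1 and a Benjamini-Hochberg adjusted p of 0.329. They include Y (3, 3 and 4 regions in controls, 4, 5 and 4 in diabetic animals) and MT (0, 0 and 1 against 3, 3 and 1). On both, counts tie between the groups, and the shares separate only because the list of control replicate 3 is longer than the lists it ties with. Shares of a library depend on one another, so the chromosomes are not independent. Chromosome 8 held 5.97% ± 0.0539 of regions in controls and 5.76% ± 0.0376 in diabetic animals, chromosome 10 held 8.26% ± 0.0757 and 8.06% ± 0.0864, and chromosome 17 held 3.18% ± 0.0556 and 3.35% ± 0.0645 (SD, n = 3 each). Among 718 windows of 1 Mb with on average at least 5 regions, diabetic counts exceeded all control counts in 38 (5.29%) and lay below them in 10 (1.39%). Chance gives 5% on each side if no counts tie, and less with ties. Another split of the libraries had 60 such windows on 1 side. The densest window, chromosome 18 from 30000001 to 31000000, held 55, 47 and 78 regions in control replicates 1 to 3 and 62, 81 and 63 in diabetic replicates 1 to 3, with 38 union regions in all 6.

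Diabetic-only regions (137) outnumbered control-only regions (25) by a ratio of 5.48, with a 95% counting interval of 3.58 to 8.39, and the larger side led by a higher ratio in 4 of the other 9 splits, by up to 12.8. A model in which libraries differ only in sensitivity gives a ratio of 4.72, inside that interval. Its sensitivities were fitted to these same lists, so a real gain in diabetic animals would be taken up as higher sensitivity. The ratio therefore cannot tell unequal detection from such a gain. At equal list lengths the ratio was 1.83 (1.27 to 2.62) against up to 2.94 in other splits. In the same model, observed over expected was 1.92 for diabetic-only regions (1.61 to 2.27) and 1.65 for control-only regions. It ranged from 0.230 to 1.86 among the 18 mixed combinations. The rule set beforehand took a value above the highest mixed combination to speak against unequal sensitivity. By that rule 1.92 against 1.86 does so, but the counting interval includes 1.86, so the number itself is left open. Of the 10 splits, 1 (the real split) gave as many group-only regions in total, 162 against 144 at most in the others, and 1 gave as many on its larger side, 137 against 133; with 10 splits no share under 0.05 can arise. A diabetes-related gain of weak peaks may contribute, and the test against unequal sensitivity did not decide it. In 78.1% to 83.1% of the regions of each list the background was the genome-wide floor. There the fold enrichment does not correct for local input, so more m6A and more RNA cannot be told apart.

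Control replicate 3 resembled the diabetic lists. Its mean Jaccard index with the controls was below that with the diabetic lists (margin -0.0587). With equal list lengths the margin was -0.0462, beyond the -0.00881 and 0.00875 of the other controls. The number of its regions is therefore not the whole cause. Equal lengths did not make covered bases equal, and its full list covered 4.11 Mb, against 3.41 and 3.33 Mb in control replicates 1 and 2. The size of its list in bases stays open. An exchange of labels with a diabetic library would leave 1 diabetic library nearer the controls, yet the lowest diabetic margin was 0.0485, and diabetic replicate 1 had a mean index of 0.751 with control replicates 1 and 2 against 0.811 with the other diabetic lists. After exchanging control replicate 3 with diabetic replicate 1 the within-group excess was 0.0172, above the 0.0156 of the labelled groups, but with equal list lengths the labelled groups had the highest excess of the 10 splits (0.0148, exact permutation p = 0.1). In the model with 1 sensitivity per library, control replicate 3 had a log sensitivity of 0.514. Diabetic replicates 1, 2 and 3 had -0.0871, 0.654 and 0.209, and control replicates 1 and 2 had -0.680 and -0.610. Unequal sensitivity, a single wrong label, a library batch and a difference between animals may each lie behind the resemblance and were not tested.

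The most variable window of 1 Mb was chromosome X from 2000001 to 3000000. Variability here is the range of counts divided by the square root of their mean plus 1. In this window 22 regions were called in diabetic replicate 3, against 4, 1 and 4 in control replicates 1 to 3 and 10 and 3 in diabetic replicates 1 and 2. Depth alone is argued against: with the fold enrichment and background they had in diabetic replicate 3, at least 21.8 of the 22 regions would be expected to pass the calling threshold at the depth of each other library, where at most 10 were called. The local input background there was 1.96 times the floor in the median in diabetic replicate 3, and 18 of the 22 regions (81.8%) lay above the floor against 18.6% of its whole list. Medians of 1.00 to 4.48 in the other libraries rest on the 1 to 10 regions called there, most of which overlapped regions of diabetic replicate 3. From 2215267 to 2216256 its background was 9.06 times the floor, against 11.7, 7.88 and 10.9 in diabetic replicate 1 and control replicates 1 and 3. Fold enrichments there were 2.72, against 1.62, 1.62 and 1.29. From 2213259 to 2214019 its background was 6.01, against 7.05, 2.55 and 5.80 in the same libraries, with folds of 2.47, against 1.58, 2.34 and 1.40. From 2105282 to 2105514, at the floor, its fold of 8.40 was below the 8.53 of diabetic replicate 1. Folds were not tested between libraries. Where only diabetic replicate 3 had a region the other backgrounds are not known, so abundant local RNA stays open, and no biological explanation was tested. Windows on chromosome 1 from 180000001 to 181000000 (9, 7 and 4 regions in controls; 5, 0 and 15 in diabetic animals) and chromosome X from 18000001 to 19000000 (13, 15 and 2; 8, 3 and 11) also varied between animals, with other libraries highest on the latter.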
